A study of Mus musculus with 2 samples.

How the data were processed

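The deposited data were raw UMI counts (unique molecular identifiers, 1 per captured RNA molecule) from 10x Chromium 3' v2 libraries of peripheral blood mononuclear cells, 1 library per genotype. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 2.1.1 on the mouse build mm10. The deposited matrices held whole numbers for 27998 genes and 737280 barcodes each, which is the complete barcode list and not a selection of cells. Before sequencing, blood of 3 mice per genotype was pooled, mononuclear cells were taken over Ficoll, red cells were lysed, and live cells negative for the red cell antigen Ter119 were sorted, with 2000 cells targeted per library. Immunoglobulin and T cell receptor genes were not among the listed genes apart from Jchain, so they could not serve as markers. How the authors' software counted reads shared by near-identical genes (Lyz1 and Lyz2, the Klra family, Bcl2a1b, Ly6c2, the haemoglobins) is not stated in the sources used here, and the values of these genes carry that uncertainty.

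Cells were called with the Cell Ranger 2 rule for 2000 expected cells: a barcode was kept when its UMIs reached the 99th percentile of the top 2000 barcodes divided by 10. This gave minimums of 784 UMIs in the mutant and 773 in the wildtype library, passed by 4524 and 5268 barcodes. Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were removed, which left 4197 and 5232. Scrublet (in scanpy) scored doublets, with 0.8% expected per 1000 cells. The threshold that Scrublet set for each library by itself marked 0.0573% of the wildtype cells, so a score above 0.2 was used in both libraries, a choice made after the scores were seen. It removed 70 mutant (1.67%) and 130 wildtype (2.48%) cells.

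The cells of both libraries were analysed together: counts were scaled to 10000 per cell, log-transformed and reduced to 2000 variable genes and 30 principal components, and Leiden clustering at resolution 1.0 was run on 15 nearest neighbours, with no integration of the libraries. A cluster was named when at least 3 genes of 1 of 19 marker sets stood among its 30 leading genes (fold of CPM, the UMIs of a gene scaled to a common total, with 20 CPM added, in genes seen in at least 10% of its cells), and the name was checked against its 10 leading genes. Of 16 clusters, 3 stayed unnamed. Cell types are therefore marker-based names, and leading genes of clusters given below were read from the clusters and not picked in advance. Classes with at least 50 cells in each library were compared: CD4 T-like, CD8 T-like, B-like, NK-like and monocyte-like cells. The last class was named by classical monocyte markers but held non-classical cells as well.

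For each of the 5 classes the UMIs of its cells were summed per library and expressed as CPM of that sum. A gene counted as measured when its sums in the 2 libraries together reached 50 UMIs. With 1 library per genotype no test, standard error or p-value can be had, and cells of 1 pool are not replicates. Shares carry exact Clopper-Pearson 95% intervals, and ratios carry exact conditional (Clopper-Pearson) 95% intervals. These cover counting error only. Where a count was 0, the limit is that of 3 counts in the total. No adjustment was made for the number of genes, so some intervals leave out 1 by chance. Gene lists (22, with the marker sets) were summarised by the median log2 ratio of their measured genes after adding 0.5 UMI, and by the percentile of that median among 10000 random lists of the same size drawn within 20 bins of mean expression. The percentile was given for lists with at least 5 measured genes and describes these 2 libraries. Not every list or every gene named by rule is reported. A list member counted as higher or lower when its 95% interval lay wholly above or below 1.

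Genes were named by rule. In each class these were the 10 higher and 10 lower genes whose interval bound nearest to 1 was farthest from it, without ribosomal, mitochondrial, haemoglobin and receptor genes and genes with provisional names. Across classes they were the 15 genes with the highest median size of log2 ratio among those off 1 in the same direction in at least 3 classes. Mvk and a few members of each list were added. The marker sets, gene lists, filters, naming rule and 16 alternative settings were chosen before the data were examined. Another 3 alternatives were chosen after seeing the data: the automatic doublet threshold of each library, the largest cluster of a class in place of all its clusters, and clustering without the leading genes that differ between the libraries inside their own cluster. Free RNA was measured in barcodes with at most 20 UMIs (395464 UMIs in 200587 barcodes of the mutant and 460573 UMIs in 200020 barcodes of the wildtype library).

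The interval method was tested on simulated data: Poisson counts drawn for each class from the joint profile of the 2 libraries at their real totals, with 200 genes altered by a known factor. Between 95.3% and 96.3% of intervals per class held the true ratio. The simulated counts followed the counting model that the intervals assume, so this coverage was built in and checks only the computation. UMIs that gather in few cells were not simulated, and the intervals of such genes can be too narrow. A 2-fold difference was recovered for 84.5% (NK-like cells) to 94.8% (CD8 T-like cells) of altered genes and a 4-fold difference for 100%, none in the wrong direction. Among unaltered genes, 4.12% to 6.16% had an interval off 1. The altered genes shifted the library totals, so the true ratio of unaltered genes was not exactly 1 (0.943 in NK-like cells). Computations used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9, and figures used matplotlib 3.10.9.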

Results

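Blood mononuclear cells of female 10-week-old C57Bl/6 mice were profiled by single-cell RNA sequencing to ask what differs in circulating cells when mevalonate kinase is impaired. The mutant mice carried the V377I allele of Mvk on 1 chromosome and the del91 deletion on the other, and the controls were wildtype. Each genotype was represented by 1 library made from the pooled blood of 3 mice. The mutant library held 14513059 UMIs and the wildtype library 15385199. After filtering, 4127 mutant cells carried 9158086 UMIs (63.1% of the library) and 5102 wildtype cells carried 11419793 (74.2%), more cells than the 2000 targeted in each case. The median mutant cell had 1955 UMIs and 873 genes (range 785 to 12850 UMIs), and the median wildtype cell 2014 UMIs and 904 genes (776 to 11198). Genotype, mouse pool and library batch were the same split of the data and cannot be told apart, so all values below describe these 2 libraries. The 95% intervals are for counting error, except those of list medians, which are over genes.

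Mvk encodes the kinase that phosphorylates mevalonate on the way to sterols and isoprenoids. Its RNA was scarce in both genotypes: 47 UMIs in mutant cells (5.13 CPM, 3.77 to 6.82) and 62 in wildtype cells (5.43 CPM, 4.16 to 6.96), a mutant to wildtype ratio of 0.945 (0.633 to 1.40). No difference in Mvk was detectable at this depth, and the ratio was 1.58 when each cell was thinned to 1000 UMIs. By class it was 0.871 (0.412 to 1.81) in CD4 T-like, 0.937 (0.459 to 1.85) in CD8 T-like and 0.760 (0.240 to 2.29) in B-like cells. NK-like and monocyte-like cells held 0 mutant and 1 wildtype UMI each, where 0 counts allow up to 7.16 and 11.3 CPM. The gene (ENSMUSG00000041939) lies on the plus strand of chromosome 5 at 114444269 to 114460591 (GRCm38), and its 11th and last exon, at 114460043 to 114460591, carries the stop codon and the 3' UTR from 114460189 on. The 3' tags count RNA that keeps this end, whatever lies upstream, and the labels do not place the deletion, so the Mvk level neither identifies nor excludes a mutant allele.

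Among the 5 compared classes, the largest difference in share was that of natural killer (NK)-like cells, which were 3.69-fold (3.16 to 4.33) less frequent in the mutant library. They made up 4.70% (4.08 to 5.39) of mutant cells (194 cells) and 17.3% (16.3 to 18.4) of wildtype cells (885 cells), a ratio of 0.271 (0.231 to 0.317). B-like cells took a larger share of the mutant library, 26.3% (24.9 to 27.6; 1084 cells) against 19.7% (18.6 to 20.8; 1006 cells), a ratio of 1.33 (1.22 to 1.45). T-like cells together took close to equal shares of all cells, 57.1% and 56.0% (ratio 1.02, 0.964 to 1.08). Monocyte-like cells made up 2.23% of mutant (92 cells) and 1.94% of wildtype cells (99 cells), a ratio of 1.15 (0.855 to 1.54). Among the lymphocyte classes alone, NK-like cells were 5.34% of the mutant and 18.6% of the wildtype cells, a ratio of 0.287. Shares are parts of the same total, so the lower NK-like share by itself raises the mutant to wildtype ratio of every other group of cells. The ratios of B-like and T-like cells include this rise, and shares without NK-like cells were not computed.

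Within the T-like cells, CD4 T-like cells were 33.0% of mutant (31.5 to 34.4; 1361 cells) and 27.7% of wildtype cells (26.4 to 28.9; 1411 cells), a ratio of 1.19 (1.11 to 1.29). CD8 T-like cells were 24.1% (22.8 to 25.4; 995 cells) and 28.4% (27.1 to 29.6; 1448 cells), a ratio of 0.849 (0.783 to 0.922). These ratios include the rise that the lower NK-like share gives, so 1.19 does not by itself show a gain of CD4 T-like cells. The T cell shares also depended on how a cell was given its class. Assigned cell by cell from marker UMIs, the ratios were 1.10 for CD4 T-like, 0.9995 for CD8 T-like and 0.333 (0.294 to 0.377) for NK-like cells. This assignment left only 490 mutant and 553 wildtype cells as CD4 T-like and made 1347 and 1666 CD8 T-like. Its T cell classes are therefore not those of the clusters. Some leading genes of the NK-like cluster were themselves lower inside it in the mutant library, among them the receptors Ncr1 (0.748, 0.666 to 0.838) and Klrb1c (0.710, 0.631 to 0.798), singled out after their values were seen. When the cells were clustered without the 36 leading genes that differed in this way, 191 mutant and 889 wildtype cells were NK-like, a ratio of 0.266 (0.226 to 0.311).

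**Figure D1:**
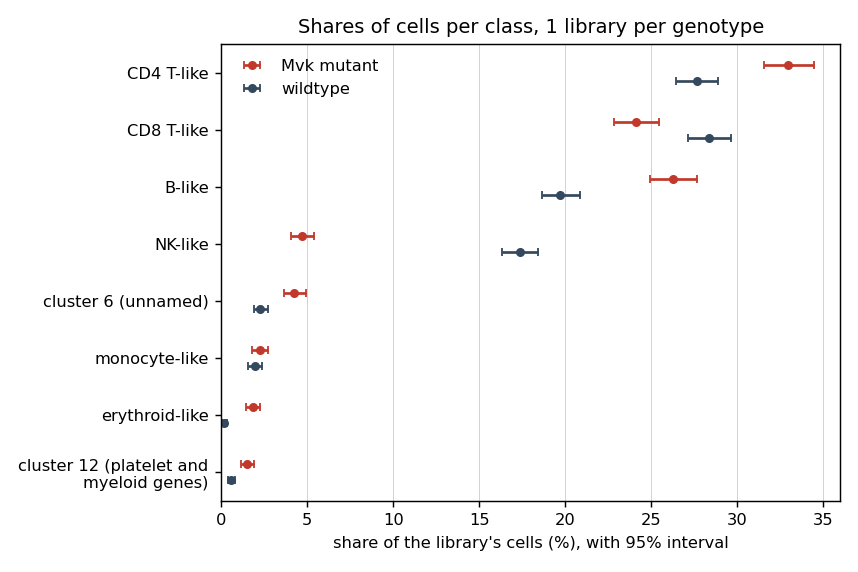
Share of each library's cells (percent, horizontal axis) in each cell class, with exact 95% intervals for counting error, for the Mvk mutant (red) and wildtype (dark) library. NK-like cells sit at 4.70% in the mutant and 17.3% in the wildtype library, and B-like cells at 26.3% and 19.7%.

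Smaller groups of cells also differed in share. A B-like cluster led by Vpreb3, Spib, Ly6d, Cd24a and Ms4a1, with Vpreb3 and Cd24a known from immature B cells, held 179 mutant and 58 wildtype cells. This was 16.5% (14.4 to 18.9) of mutant and 5.77% (4.41 to 7.39) of wildtype B-like cells, a ratio of 2.86 (2.12 to 3.92). Its share of all cells had a ratio of 3.82 (2.82 to 5.22), and 3.82 (2.80 to 5.30) in the clustering without differing leading genes. A cluster of B lineage cells that no marker set named (Atf3, Zbtb32, Bhlhe41, Mzb1 and Ms4a1 among its leading genes) made up 4.24% of mutant (175 cells) and 2.27% of wildtype cells (116 cells), a ratio of 1.87 (1.47 to 2.38). B-like cells with this cluster added were 30.5% and 22.0%. A CD8 T-like cluster had Cxcr3, the granzyme gene Gzmm, Ly6c2, Cd160, Ikzf2, Il2rb and Klrc1 among its leading genes. It was a smaller part of the CD8 T-like cells in the mutant library: 22.4% (223 cells) against 29.4% (426 cells), a ratio of 0.762 (0.645 to 0.898).

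Red cell and platelet signals were more frequent in the mutant library although red cells had been lysed and Ter119-positive cells sorted out. Erythroid cells numbered 75 of the mutant and 8 of the wildtype cells, 1.82% and 0.157%, a ratio of 11.6 (5.59 to 27.8). A cluster that mixed platelet genes (Ppbp, Pf4, Gng11) with dendritic cell and monocyte genes (Siglech, Cd209a) and Retnla held 62 mutant (1.502%) and 29 wildtype cells (0.568%), a ratio of 2.64 (1.67 to 4.26). Its boundary moved with the clustering, and other clusterings gave smaller clusters with ratios of 11.2 to 16.1, such as 26 against 2 cells at resolution 0.5, while cell-by-cell classes gave 16.7 for platelet-like cells. Neutrophil-like cells (2 mutant, 11 wildtype) and basophil-like cells (17 and 15) were too few for a comparison of genes.

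Gene by gene, few measured genes were 2-fold or more apart between the genotypes. Of 6822 measured genes in CD4 T-like, 7106 in CD8 T-like, 5965 in B-like, 4637 in NK-like and 1563 in monocyte-like cells, 32, 24, 32, 27 and 19 were at least 2-fold higher in the mutant with an interval off 1. Those at least 2-fold lower numbered 12, 17, 21, 70 and 12, with the most in NK-like cells. That class had 419025 mutant and 1612397 wildtype UMIs, so low mutant counts can give large ratios by counting error. In the simulation 6.16% of its unaltered genes had an interval off 1, the highest share. There the altered genes had moved the true ratio of unaltered genes to 0.943, so this share does not measure counting error alone. How many of the 70 would arise by counting error was not computed. The median log2 ratio of all measured genes lay between -0.05 and 0.04 in each class. In at least 3 classes, 62 genes were higher and 34 lower in the mutant.

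Genes of NK cells, platelets and red cells were among those that differed in several classes, and they also differed in near-empty droplets. Gzma, the gene of the cytotoxic protease granzyme A (ENSMUSG00000023132; chromosome 13, 113093825 to 113100981, minus strand), was lower in the mutant in all 5 classes, at ratios of 0.273 (0.225 to 0.328) in CD4 T-like, 0.574 (0.512 to 0.643) in CD8 T-like, 0.208 (0.163 to 0.264) in B-like, 0.869 (0.846 to 0.894) in NK-like and 0.127 (0.0612 to 0.240) in monocyte-like cells. The chemokine genes Ccl4 and Ccl5 were each lower in 4 classes, while Ccl5 was higher in NK-like cells (1.17, 1.14 to 1.19). In barcodes with at most 20 UMIs, Gzma stood at 508 CPM in the mutant and 2445 in the wildtype library (ratio 0.208), Ccl5 at 1826 and 5767, Ccl4 at 185 and 584, and the granule protein gene Nkg7 at 536 and 1225. After subtraction of the free RNA profile the ratios in B-like cells were 0.968 for Ccl5 (0.449 before) and 0.279 for Gzma. The monocyte-like ratio of Gzma was 0.231 after thinning, and that of Ccl5 (0.279) ranged from 0.126 after the subtraction to 0.476 with cell-by-cell classes.

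On the higher side, platelet chemokine genes Pf4 and Ppbp and the G protein subunit gene Gng11 stood at ratios of 3.53, 3.94 and 4.82 in CD4 T-like, 4.04, 4.13 and 4.81 in CD8 T-like, and 3.84, 3.92 and 3.78 in monocyte-like cells, with Pf4 at 3.53 in B-like cells. Retnla, which encodes the secreted resistin-like molecule alpha (ENSMUSG00000061100; chromosome 16, 48842551 to 48844461, plus strand), had 76 mutant against 1 wildtype UMI in CD4 T-like cells (ratio 83.9, 14.6 to 3357), a ratio of 15.6 (6.77 to 44.3) in CD8 T-like cells and 23.9 (6.28 to 203) in B-like cells. The B-like value was 1.55 with cell-by-cell classes and the CD8 T-like value 5.28 after thinning. Among the platelet genes, Gng11 in CD4 T-like cells ranged from 2.37 with cell-by-cell classes to 8.19 in the largest cluster, where Pf4 was at 5.67, while Ppbp in CD8 T-like cells was at 9.29 after thinning and Pf4 in B-like cells at 5.72 after free RNA subtraction. Free RNA held these genes at 182 (mutant) against 8.68 CPM for Retnla, 157 against 60.8 for Pf4, 147 against 41.3 for Ppbp and 126 against 43.4 for Gng11. Haemoglobin RNA was higher as well: Hba-a1 was 17.2-fold and 20.01-fold higher in CD4 T-like and B-like cells, and 16.5-fold in free RNA. The lists of erythroid and platelet RNA had median log2 ratios of 3.99 and 1.87 in CD4 T-like, 3.76 and 2.002 in CD8 T-like, 3.82 and 1.78 in B-like and 4.20 and 1.93 in monocyte-like cells. In NK-like cells erythroid RNA stood at 5.80 (Hba-a1 69.9-fold higher, more than in free RNA), with the single measured platelet gene Gp1bb at -0.99. Each of the 4 measured erythroid genes was higher in every class, and no gene of the neutrophil list was measured in any.

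**Figure D2:**
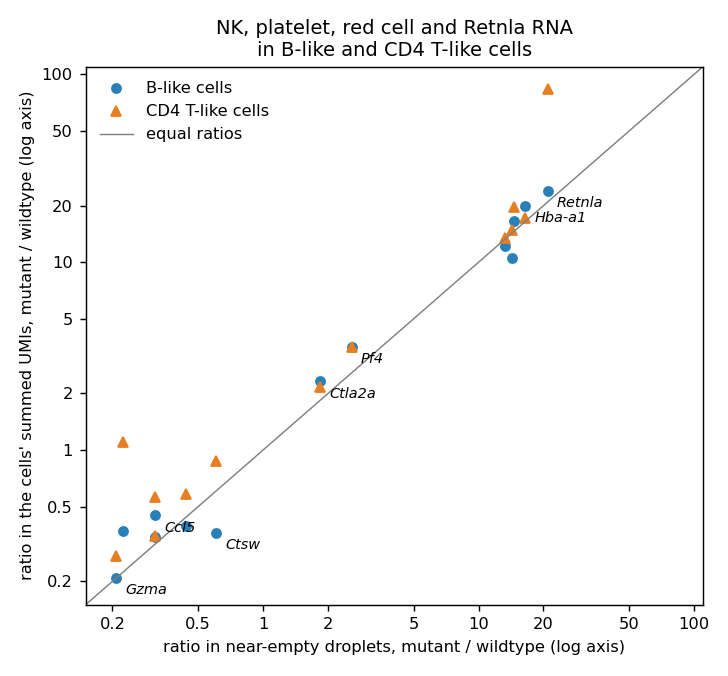
Mutant to wildtype ratio of each gene in near-empty droplets (at most 20 UMIs, horizontal axis) against its ratio in the summed UMIs of B-like (circles) and CD4 T-like (triangles) cells (vertical axis), both axes logarithmic, with the line of equal ratios. Gzma in B-like cells lies at 0.208 on both axes, Retnla at 21.0 in droplets and 23.9 in B-like cells.

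Other genes were also off 1 in the same direction in several classes, and for most of them free RNA differed the same way. Cebpb, a transcription factor of myeloid and stress responses, stood at 2.52 in CD4 T-like, 2.37 in CD8 T-like, 2.62 in B-like and 1.79 in monocyte-like cells, with similar free RNA of 40.5 and 39.1 CPM. The lysozyme gene Lyz2 was higher in all 5 classes (1.76, 1.90, 1.90, 2.08 and 1.24 in CD4 T-like, CD8 T-like, B-like, NK-like and monocyte-like cells), beside 1049 against 662 CPM of free RNA. With cell-by-cell classes the NK-like value was 1.03 and the B-like value 1.26. After free RNA subtraction the B-like value was 21.2, but almost no wildtype UMIs were left, so that value does not measure the difference. Ctla2a, which encodes an inhibitor of cysteine proteases, was higher in 4 classes, from 1.73 in NK-like to 3.69 in monocyte-like cells, and stood at 0.924 in CD8 T-like cells, where it turned to 1.51 with cell-by-cell classes and 2.32 in the largest cluster. Tsc22d1, a leucine zipper transcription regulator and a leading gene of the cluster with platelet genes, was higher in 4 classes, from 1.33 in B-like and 1.58 in CD8 T-like to 2.65 in NK-like cells (1.44 after thinning) and 6.19 in monocyte-like cells (1.86 to 2.05 in the wider classes described below). Hsph1, a heat shock protein gene, stood at 1.53, 1.86 and 2.77 in CD4 T-like, CD8 T-like and B-like cells, and Pkig, an inhibitor of protein kinase A, at 1.94, 1.30 and 2.40 in CD4 T-like, B-like and monocyte-like cells (1.28 to 1.30 in the wider monocyte-like classes). In free RNA of the mutant and wildtype library, Ctla2a stood at 359 and 195 CPM, Tsc22d1 at 106.2 and 34.7, Hsph1 at 40.5 and 15.2, Pkig at 126 and 56.5, Ms4a1 at 391.9 and 232 and Nabp1 at 25.3 and 73.8. The B cell gene Ms4a1 (CD20) was higher in CD8 T-like (1.83), NK-like (2.03, or 1.25 with the automatic doublet thresholds) and B-like cells (1.13, but 0.912 in the largest B-like cluster). Nabp1, which encodes a single-stranded DNA binding protein, was lower in all 5 classes: 0.748, 0.691, 0.419, 0.450 and 0.530 in CD4 T-like, CD8 T-like, B-like, NK-like and monocyte-like cells, the last at 0.697 to 0.812 in the wider classes.

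Among lower genes of NK-like cells, Ly6c2, which encodes a GPI-anchored surface protein (ENSMUSG00000022584; chromosome 15, 75108158 to 75111970, minus strand), stood at 274 CPM in mutant and 798 in wildtype cells, a ratio of 0.344 (0.282 to 0.417), and 0.573 with cell-by-cell classes. The Ly49 family receptor gene Klra9 (ENSMUSG00000033024; chromosome 6, 130178675 to 130193112, minus strand) stood at 592 and 1263 CPM (0.468, 0.409 to 0.535). The chemokine genes Ccl3 and Ccl4 were lower at 0.566 (0.462 to 0.688) and 0.617 (0.567 to 0.669). Kcnj8, a potassium channel gene, was at 0.266 (0.119 to 0.522). Lower values on few UMIs were found for Rdm1 (3 against 71 UMIs, 0.163), for the phosphatidylserine synthase gene Ptdss1 (4 against 68, 0.226) and Phospho2 (3 against 55, 0.210). Thinning gave 0.139 for Phospho2. With cell-by-cell classes the ratios of Rdm1 (0.358) and Ptdss1 (0.414) were nearer to 1, and so was that of the anti-apoptotic gene Bcl2a1b, 0.664 against 0.341 (0.166 to 0.632).

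Among higher genes of NK-like cells, Cxcr4, the receptor of the chemokine Cxcl12 (ENSMUSG00000045382; chromosome 1, 128588199 to 128592293, minus strand), was at 117 CPM in mutant and 45.3 in wildtype cells, a ratio of 2.58 (1.76 to 3.76). Cmtm7, a tetraspan membrane protein gene, stood at 2.12 (1.54 to 2.91), the LIM domain gene Limd1 at 2.27 (1.52 to 3.35), the phosphatase regulator Ppp1r10 at 2.36 (1.44 to 3.79) and the inositol phosphate kinase gene Itpk1 at 2.43 (1.39 to 4.16). Ppcdc, of coenzyme A synthesis, was at 2.77 (1.55 to 4.88) and at 4.22 after thinning. The interferon-induced gene Ifi27l2a was at 1.98 (1.38 to 2.83), and 3.21 at resolution 2. Its level in the cells, 117 CPM in mutant and 58.9 in wildtype, was far below its free RNA of 698 and 497 CPM. Free RNA stood at 129 and 102 CPM for Cxcr4, 111 and 67.3 for Cmtm7 and 48.0 and 49.9 for Limd1. How far free RNA adds to these ratios was not determined. The mutant sum of this class, 419025 UMIs in 194 cells, was the limit to precision.

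In monocyte-like cells, the balance of marker UMIs differed between the libraries: 52.2% (41.5 to 62.7) of mutant and 31.3% (22.4 to 41.4) of wildtype cells had more classical than non-classical marker UMIs. Within 3 UMIs of this split lay 8 mutant and 12 wildtype cells. Chil3, Ly6c2 and Cd14, described below, are among the classical markers and Stap1 among the non-classical ones. A shift of such genes within the cells would move this balance as a different mix would, so the balance cannot tell them apart. Non-classical markers had a median log2 ratio of -0.35 (1 of 19 higher, 7 lower) and classical markers one of 0.28 (8 of 16 higher, 0 lower). Of the 10 higher genes named by rule, Pf4, Ppbp, Gng11, Ctla2a and Tsc22d1 are described above. Chil3, which encodes a chitinase-like protein (ENSMUSG00000040809; chromosome 3, 106147554 to 106167564, minus strand), stood at 1501 CPM in mutant and 508 in wildtype cells, a ratio of 2.95 (2.42 to 3.63), with free RNA of 15.2 and 17.4 CPM. Lyz1 was at 6.55 (128 against 19 UMIs, 4.03 to 11.2), although like shares of cells held it (17.4% of mutant and 16.2% of wildtype cells), so its UMIs sat in few cells. Ly6c2 was at 2.17 (1.70 to 2.77) and Cd14, the lipopolysaccharide co-receptor, at 2.79 (1.52 to 5.40), which ranged from 1.66 with cell-by-cell classes to 5.74 after thinning. Lower genes were Dusp1, a MAP kinase phosphatase (0.554, 0.456 to 0.6699), the cytokine gene Il1b (12 against 41 UMIs, 0.285, 0.136 to 0.552), the transglutaminase gene Tgm2 (0.349), the adaptor Stap1 (0.449), the acyltransferase Agpat4 (0.506), the tetraspanin Cd82 (0.451) and the RNA helicase gene Ddx39b (0.423, and 0.170 after thinning). Nkg7 was at 0.299 (0.143 to 0.583), and at 1.2 with cell-by-cell classes. In 7 alternative settings with recomputed gene values the class was wider, with 117 to 128 cells in each library. There Ly6c2 stood at 1.11 to 1.20, Cd14 at 1.98 to 2.21, Il1b at 0.673 to 0.794, Pf4 at 1.89 to 2.09, Lyz1 at 9.95 to 10.5 and Chil3 at 2.53 to 2.75. With cell-by-cell classes Pf4 was at 1.51. The clustering without differing leading genes also gave a wider class (119 mutant and 125 wildtype cells), but only shares were recomputed for it.

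Among the lists with at least 5 measured genes, that of the type I interferon response stood highest in monocyte-like cells, with a median log2 ratio of 0.36 (0.15 to 0.84; percentile 99.99) and 8 of 16 measured members higher and 0 lower. Among the members were Bst2, which tethers virions (1.82), the transcription factor Irf7 (1.83), the chaperone Rtp4 (1.81), Phf11b (2.29), Slfn2 (1.39), the DNA sensor Ifi204 (1.42), Ifi27l2a (1.68) and Ifitm3 (1.16). In the 7 settings with a wider class this median was 0.18 to 0.23, with an interval over genes that included 0 in 5 of them, and with cell-by-cell classes it was 0.22 (-0.02 to 0.67). In the 68 mutant and 88 wildtype cells with fewer than 2 platelet UMIs it was 0.04 (-0.36 to 0.82). In other classes the list was at -0.02 (percentile 27.1, 3 of 21 higher, 1 lower) in CD4 T-like, 0.08 (89.8, 4 of 22 higher) in CD8 T-like, 0.12 (89.1, 4 of 19 higher, 1 lower) in B-like and 0.10 (91.8, 1 of 12 higher) in NK-like cells. Examples in CD8 T-like cells were Ifi27l2a (1.55), Irf7 (1.40), Isg20 (2.04) and Ifitm3 (1.74), the last beside free RNA of 215 and 109 CPM. The list of S100 and granule proteins had a median of 0.25 in monocyte-like cells (-0.35 to 0.76; 99.6, 4 of 8 higher, 1 lower), or 0.28 to 0.38 in the wider classes. Higher members were S100a6 (1.32), S100a11 (1.46) and Wfdc17 (1.70), with the oxidase subunit gene Cybb lower (0.783).

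**Figure D3:**
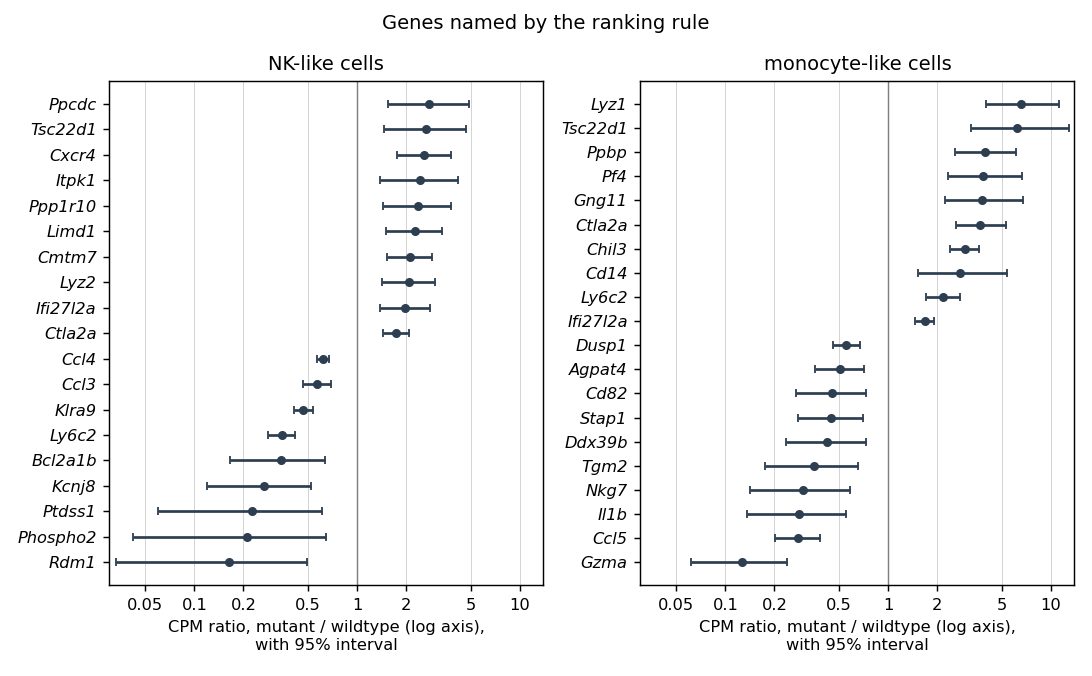
Mutant to wildtype ratio of CPM (logarithmic horizontal axis) with 95% intervals for counting error, for genes named by rule in NK-like cells and in monocyte-like cells. In NK-like cells Cxcr4 lies at 2.58 and Ly6c2 at 0.344, and in monocyte-like cells Chil3 lies at 2.95 and Gzma at 0.127.

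In B-like cells, Sox4, a transcription factor of early lymphocyte stages (ENSMUSG00000076431; chromosome 13, 28948919 to 28953713, minus strand), stood at 2.67 (1.68 to 4.36), the signalling adaptor Tifa at 2.01 (1.58 to 2.58) and Fam129c at 2.29 (1.57 to 3.41). In the largest B-like cluster Tifa was at 1.14, while Sox4 stayed at 2.65 and Fam129c at 1.80. Mtmr14, a phosphoinositide phosphatase gene, was at 3.44 (2.14 to 5.73), and Wfdc21 at 2.81 (1.56 to 5.31), but 0.375 in the largest cluster. Lower genes other than those of NK cells were the cholesterol efflux pump Abca1 (ENSMUSG00000015243; chromosome 4, 53030787 to 53159895, minus strand) at 0.473 (0.295 to 0.742), the guanine nucleotide exchange factor gene Dock10 at 0.594 (0.481 to 0.731), the suppressor of cytokine signalling Socs3 at 0.510 (0.351 to 0.734) and the carbonic anhydrase gene Car2 at 0.432 (0.264 to 0.691). The granule genes Nkg7 (0.393), Ctsw (0.361), Ccl4 (0.345) and Gzmb (0.370) were lower as well. Ccl4 ranged from 0.161 with doublets kept to 0.809 with cell-by-cell classes. Ctsw ranged from 0.0853 after free RNA subtraction to 0.582 after thinning, and Nkg7 was at 0.242 after the subtraction. The subtraction took 89.4% of the 17 mutant Ctsw UMIs, so the low end for Ctsw rests on very few counts. The Gzmb value turned above 1 at resolution 0.5 (1.27), with the automatic doublet thresholds (1.30) and after free RNA subtraction (2.35). The last value rests on very few counts, since the subtraction took 93% of the 37 wildtype UMIs.

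Several antigen presentation genes were slightly lower in mutant B-like cells. The interferon gamma and antigen presentation list had a median of -0.17 (-0.22 to -0.02; percentile 0.04), with 8 of 21 members lower and 0 higher: H2-Aa (0.875), H2-Ab1 (0.890), H2-Eb1 (0.853), H2-DMa (0.858), H2-DMb1 (0.753), the invariant chain gene Cd74 (0.937), the immunoproteasome subunit Psmb8 (0.843) and Socs3. This median was -0.07 in the largest B-like cluster or with doublets kept, and -0.06 with the automatic doublet thresholds. It was -0.01 (27.6, 4 of 22 higher, 5 lower) in CD4 T-like, 0.07 (85.1, 5 of 23 higher, 3 lower) in CD8 T-like, 0.05 (82.0, 3 of 18 higher, 2 lower) in NK-like and -0.08 (19.2, 1 of 13 higher, 3 lower) in monocyte-like cells. The NK-like value was -0.14 with the automatic doublet thresholds. In monocyte-like cells Ifi47 was at 1.90 and the class I gene H2-K1 at 0.676.

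In CD4 T-like cells, many of the named genes were transcripts known from other blood cell types. Cd74 stood at 299 CPM in mutant and 143 in wildtype cells (2.098, 1.86 to 2.37) and the B cell receptor signalling gene Cd79a at 2.50 (1.83 to 3.43), beside free RNA of 6827 against 5124 CPM for Cd74 and 827 against 484 for Cd79a. The signalling adaptors Fcer1g (0.386, 0.298 to 0.495, or 0.245 after free RNA subtraction) and Tyrobp (0.613, 0.493 to 0.760), the granule gene Nkg7 (0.584, 0.505 to 0.674) and the chemokine gene Ccl4 (0.348, 0.249 to 0.479) were lower. Ccl5 stood at 0.563 (0.521 to 0.608) and the NK receptor gene Klre1 at 0.311 (0.144 to 0.620), or 0.526 with cell-by-cell classes. Among genes that are not tied to another blood cell type, Klf11, a Kruppel-like transcription factor, was at 3.02 (1.64 to 5.87), the ubiquitin ligase subunit Fbxl20 at 0.427 (0.255 to 0.695), and B9d2, of the primary cilium, at 0.428 (0.238 to 0.740). Cd72, a surface receptor of B cells, was at 0.504 (0.332 to 0.753) and the chemokine gene Ccl6 at 3.14 (1.63 to 6.44), or 0.329 and 6.13 after the subtraction. Ifitm1 stood at 5.76 (47 against 9 UMIs), but 0.441% of mutant and 0.496% of wildtype cells held it, so a few cells carry the value. Ifitm1 was at 1.11 to 1.32 in 5 alternative settings and at 0.689 with all barcodes of at least 500 UMIs. It was at 9.32 after free RNA subtraction, 3.66 after thinning and 3.22 as a mean over cells.

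In CD8 T-like cells, several NK receptor and effector genes were lower in the mutant, where the CD8 T-like cluster with Cxcr3 and Gzmm was smaller (0.762) and free RNA of the same genes lower. Klra8, Klra4, Klra9 and Klra7, genes of the Ly49 family, stood at 0.162 (0.0570 to 0.374), 0.180 (0.0633 to 0.419), 0.337 (0.194 to 0.558) and 0.496 (0.396 to 0.618), and the receptor gene Klrc2 at 0.436 (0.315 to 0.594). Ccl5 stood at 2983 CPM in mutant and 4458 in wildtype cells (0.669, 0.651 to 0.688), Ccl4 at 0.491 (0.384 to 0.622), Fcer1g at 0.535 (0.450 to 0.634) and Tyrobp at 0.583 (0.485 to 0.699). In near-empty droplets of the mutant and wildtype library, Klra8 stood at 60.7 and 158.5 CPM, Klra4 at 53.1 and 184.6, Klra9 at 22.8 and 178.04, Klra7 at 98.6 and 165.01, Klrc2 at 30.3 and 82.5, Fcer1g at 334 and 734 and Tyrobp at 429.9 and 777. Several of these moved with the definition of the class: thinning gave 0.0667 for Klra8, the largest CD8 T-like cluster gave 0.187 for Klrc2, Klra4 reached 0.430 and Klra9 0.124 among the alternatives, and Gzma was 0.275 to 0.307 at resolution 2, with cell-by-cell classes or in the largest cluster. On the higher side stood Ddit4, an inhibitor of mTORC1 (42.1 against 17.2 CPM, 2.45, 1.78 to 3.38), the clock and replication gene Timeless (3.81, 2.08 to 7.30), and the invariant chain gene Cd74 (1.65, 1.47 to 1.85).

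The lymphocyte activation list had a median of -0.21 (-0.44 to 0.09; percentile 0.06) in CD8 T-like cells, with 4 of 16 members lower and 0 higher: the adhesion receptor Cd44 (0.694), the chemokine receptor Cxcr3 (0.753), the transcription regulator Id2 (0.891) and Gzma. In the largest CD8 T-like cluster alone it was -0.01. The list was at -0.13 (2.96, 1 of 14 higher, 2 lower) in CD4 T-like, -0.05 (12.4, 3 of 12 higher, 4 lower) in B-like, -0.19 (4.28, 4 of 13 lower) in NK-like and -0.27 (3.67, 3 of 6 lower) in monocyte-like cells, with the B-like value at 0.21 under the automatic doublet thresholds. Its members Gzma and Gzmb were also lower in free RNA of the mutant library (508 against 2445 and 53.1 against 237 CPM). In NK-like cells Tnfrsf9 (0.524), Gzmb (0.740) and Id2 (0.732) were lower, and in B-like cells Batf (1.83), Cd44 (1.76) and Myc (1.34) were higher while the immediate early receptor gene Nr4a1 (0.657) was lower.

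The enzymes of the mevalonate and sterol pathway, the process in which Mvk acts, had few members off 1 in the classes where they were measured. Their median log2 ratio was -0.02 (percentile 45.6, 0 of 13 off 1) in CD4 T-like, -0.15 (-0.26 to -0.07; 10.2, 1 of 12 lower) in CD8 T-like and 0.02 (44.3, 1 of 8 higher) in B-like cells, and 3 genes in NK-like cells gave -0.26. The lower gene was Mvd (0.605, 0.361 to 0.983) and the higher one Acat2 (1.80). Hmgcs1, which sterol-sensing transcription factors induce, stood at 1.20 in CD4 T-like, 0.893 in CD8 T-like and 0.888 in B-like cells, each with an interval that included 1. Fdps, which makes farnesyl diphosphate, stood at 1.37, 0.756 and 1.06 in the same classes. No gene of this list was measured in monocyte-like cells. The CD8 T-like median ranged from -0.25 in the largest cluster to -0.0035 with cells thinned to 1000 UMIs.

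Sterol transport and control genes were at -0.02 (43.8, 1 of 11 higher, 1 lower) in CD4 T-like, 0.0021 (44.5, 0 of 12 off 1) in CD8 T-like, 0.03 (41.9, 2 of 10 lower) in B-like and -0.08 (41.6, 0 of 6 off 1) in NK-like cells, with 1 gene at 0.18 in monocyte-like cells. The exceptions were the efflux pumps Abca1 and Abcg1 (0.567) in B-like cells and the regulator Srebf2 (1.35) and Npc2 (0.897) in CD4 T-like cells. Genes of prenylation (the attachment of isoprenoid lipids to proteins) and of other isoprenoid use were at 0.14 (89.4, 0 of 11 off 1) in CD4 T-like, 0.04 (56.5, 0 of 12) in CD8 T-like and -0.03 (24.6, 1 of 9 higher) in B-like cells. They were at -0.25 over 4 genes in NK-like cells, and none was measured in monocyte-like cells. The CD4 T-like value was -0.01 in the largest cluster, and the higher gene in B-like cells was the CAAX protease gene Zmpste24 (1.76).

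Genes known to respond to statins, which block the pathway upstream of Mvk, were at 0.01 (57.9, 1 of 6 higher, 2 lower), -0.12 (8.96, 1 higher, 3 lower), 0.19 (93.2, 1 higher, 1 lower), -0.12 (19.8, 0 off 1) and -0.17 (10.1, 1 higher) in CD4 T-like, CD8 T-like, B-like, NK-like and monocyte-like cells. Among them the transcription factor Klf2 stood at 0.934, 0.931 and 1.04 in the first 3 of these classes, Klf4 at 0.509 in CD8 T-like cells, and the haem oxygenase gene Hmox1 at 1.53 in monocyte-like cells.

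Inflammasome and interleukin-1 genes, chosen because mevalonate kinase deficiency is an inflammatory disease, had at most 1 member off 1 in each direction in CD4 T-like, CD8 T-like, B-like and NK-like cells. The medians were -0.03 (28.1, 1 of 7 higher, 1 lower) in CD4 T-like, -0.07 (13.4, 1 of 7 higher) in CD8 T-like, 0.11 (63.0, 0 of 9 off 1) in B-like and 0.17 (90.2, 1 of 7 higher) in NK-like cells, and -0.28 over 3 genes in monocyte-like cells. The inflammasome adaptor Pycard was at 0.865 in CD4 T-like and 1.28 in NK-like cells, and Txnip, a thioredoxin inhibitor, at 1.27 in CD4 T-like and 1.24 in CD8 T-like cells. The NF-kB and cytokine list was at 0.03 (62.6, 1 of 13 higher, 2 lower), 0.01 (39.2, 2 of 15 lower), 0.06 (64.5, 1 of 13 higher, 2 lower), -0.20 (3.73, 1 of 13 higher, 3 lower) and 0.03 (64.3, 2 of 9 higher, 2 lower) in CD4 T-like, CD8 T-like, B-like, NK-like and monocyte-like cells. Its feedback inhibitor Nfkbia was at 1.27 in B-like cells, and Bcl2a1b at 0.668 in monocyte-like cells. S100 and granule genes outside monocyte-like cells were at 0.02 (60.0, 2 of 6 higher) in CD4 T-like, -0.07 (9.38, 1 of 7 higher, 2 lower) in CD8 T-like, 0.13 (90.8, 4 of 9 higher, 1 lower) in B-like and 0.11 (79.9, 1 of 6 higher) in NK-like cells, with S100a6 at 0.774 in CD8 T-like and 1.54 in B-like cells.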

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

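The tests of NK cells lost in cell calling, of dilution, of free RNA in B-like, CD4 T-like and monocyte-like cells and of platelets on monocytes were chosen only after the result was seen; those of pools, doublets and the monocyte mix were chosen before. The first versions of the tests of cell calling and of free RNA in B-like and CD4 T-like cells were replaced after their values were seen, and the rules for reading the interferon and free RNA tests were made stricter.

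Haemoglobin-rich barcodes outside the compared cells were far more frequent in the mutant library. There were 292 mutant barcodes past the UMI minimum with fewer than 200 genes, against 19 in the wildtype library, and 361 against 26 with haemoglobin over 50% of their UMIs. Below the minimum, from 100 UMIs up, 167 of 3795 mutant and 19 of 2226 wildtype barcodes had haemoglobin over 50%.

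Some genes had intervals on opposite sides of 1 in different classes, and the difference between classes was not tested. Cd74 was higher in CD4 T-like (2.098), CD8 T-like (1.65) and NK-like cells (1.54) and lower in B-like (0.937) and monocyte-like cells (0.777). Ccl5 was higher in NK-like cells (1.17) and lower in CD4 T-like (0.563), CD8 T-like (0.669), B-like (0.449) and monocyte-like cells (0.279). Ly6c2 was higher in monocyte-like cells (2.17) and lower in CD8 T-like (0.855), B-like (0.598) and NK-like cells (0.344). Car2 was higher in CD8 T-like (1.70) and NK-like cells (1.37) and lower in CD4 T-like (0.613) and B-like cells (0.432). Klra7 stood at 1.18 in NK-like and 0.496 in CD8 T-like cells, Limd1 at 2.27 and 0.785 in these classes, and Cd72 at 1.15 in B-like and 0.504 in CD4 T-like cells.

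The lower share of NK-like cells was weighed first. Loss of NK cells in cell calling was excluded as the whole cause: NK marker genes took 0.579% of all non-haemoglobin UMIs of the mutant and 1.42% of the wildtype library over every barcode, a ratio of 0.406 (0.403 to 0.409), and 0.398 (0.391 to 0.404) in barcodes below the minimum. Dilution by red cells and platelets was excluded as well, since NK-like cells per T-like cell had a ratio of 0.266 (0.227 to 0.311). With 1 library per genotype, a difference between the pools, the bleeding, the sort or the library cannot be told apart from one of genotype, and genotype remains an open, untested explanation.

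The NK cell genes that were lower, and the red cell, platelet and Retnla RNA that was higher, in mutant B-like cells are in part consistent with free RNA in the droplets: over 13 genes, the level in the cells as a multiple of that in near-empty droplets had a median mutant to wildtype ratio of 1.13 (middle 50% of genes 0.919 to 1.26). In CD4 T-like cells free RNA could not be decided, since this ratio was 1.31 (1.07 to 1.36) over the 11 genes off 1 in the same direction and 1.33 (1.10 to 1.46) over all 13, with Gzmb (52 UMIs in each library) and Ctsw (0.879) not lower there beyond counting error. Subtraction of the free RNA profile at the lowest share that markers allow took 86.6% of the mutant and 90.1% of the wildtype Gzma UMIs of B-like cells and 56.0% and 53.5% of those of CD4 T-like cells. Taking off part of a profile with a like ratio leaves that ratio in place, so the 0.279 and 0.263 that remained for Gzma do not decide, and a difference within the cells or a larger free share stays open. Doublets of B and NK cells were excluded for Gzma: 8.12% of its UMIs in wildtype B-like cells sat in cells with 5 or more (1 cell), while the median NK-like cell held 29.

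For the interferon genes of monocyte-like cells, free RNA at the lowest share that markers allow was excluded as the whole cause. The subtraction took a median of 3.59% of the mutant and 5.08% of the wildtype UMIs of these genes and left a median log2 ratio of 0.40 (0.17 to 0.86). In free RNA itself 15 genes of the list had a median log2 ratio of 0.096. B cell markers gave larger free shares (46.1% in mutant and 78.7% in wildtype cells), and subtraction at a larger share was not run. Platelets captured with monocytes cannot be told apart from a difference in the cells: without cells holding at least 2 platelet UMIs (24 mutant and 11 wildtype cells removed) the median was 0.039, with an interval of -0.36 to 0.82 over 16 genes that is too wide to decide. A different mix of monocytes stays open too, since in the 48 mutant and 31 wildtype cells with more classical than non-classical marker UMIs the median was 0.16 (-0.12 to 0.48) and in the other 44 and 68 cells 0.40 (-0.12 to 1.02), both too wide to decide. The biological explanation by genotype was not tested apart from the pools.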

How the results depend on the processing

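The automatic doublet thresholds, the largest cluster of each class and the clustering without differing leading genes are 3 alternatives chosen after seeing the data. No paired analysis was possible because each genotype had 1 library, and nothing could be left out in turn for the same reason. Of the values recomputed under an alternative, 55 of 67 for shares, 1640 of 1794 for named genes, 1453 of 1466 for list medians, 9 of 10 for Mvk and 8 of 10 for cell numbers stayed within their intervals (over genes for list medians, for counting error otherwise). Those that moved further were 12, 147, 13, 1 and 2, and another 7 gene values with an interval off 1 turned to the other side of 1. Depth limited NK-like cells on the mutant side (194 cells) and monocyte-like cells (1563 measured genes) most.

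At most 5% mitochondrial UMIs left 3931 mutant and 4900 wildtype cells, fewer by construction. Cell-by-cell classes, with far fewer CD4 T-like cells, gave share ratios of 1.10 for CD4 T-like, 0.9995 for CD8 T-like and 0.333 for NK-like cells. They turned Nkg7 in monocyte-like cells to 1.2. Thinning to 1000 UMIs, which leaves fewer counts, gave 1.58 for Mvk and -0.0035 for the mevalonate and sterol list in CD8 T-like cells. With at least 500 UMIs Ifitm1 in CD4 T-like cells turned to 0.689. In the largest B-like cluster Wfdc21 turned to 0.375 and Ms4a1 to 0.912. Values whose interval held 1 were not counted as turned, such as Ctla2a in CD8 T-like cells. Gzmb in B-like cells turned to 1.27 at resolution 0.5, 1.30 with automatic doublet thresholds and 2.35 after free RNA subtraction, the last on very few remaining wildtype UMIs. The cause was not tested except where the construction is named.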

Other observations

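The tests of NK cell maturity, T cell RNA, class II genes and Retnla below were written before the values they measure were seen, but chosen after the patterns that prompted them, and the lists of mature and less mature NK cell genes were written after the named genes. Some protein folding genes were higher in mutant lymphocytes. The unfolded protein and heat shock list had medians of 0.11 (-0.02 to 0.19; percentile 99.1, 7 of 20 higher, 0 lower) in CD4 T-like, 0.12 (0.03 to 0.22; 99.3, 4 of 20 higher) in CD8 T-like, 0.17 (-0.03 to 0.42; 99.5, 8 of 20 higher) in B-like and 0.06 (-0.13 to 0.17; 93.0, 2 of 20 higher, 1 lower) in NK-like cells, and 0.07 (83.0, 1 of 14 higher, 1 lower) in monocyte-like cells. The chaperone gene Hspa8 stood at 1.16, 1.17, 1.35 and 1.41 and its partner Dnaja1 at 1.27, 1.34, 1.34 and 1.33 in CD4 T-like, CD8 T-like, B-like and NK-like cells. In B-like cells Hspd1 was at 1.63 and Herpud1, of protein degradation at the endoplasmic reticulum, at 1.68, while in NK-like cells the endoplasmic reticulum chaperone Hspa5 was lower at 0.792. The list of oxidative phosphorylation subunits had medians slightly above 0 in CD4 T-like (0.08, 0.04 to 0.12; 99.8, 10 of 34 higher, 1 lower), CD8 T-like (0.06, 0.03 to 0.09; 96.3, 4 higher) and B-like cells (0.11, 0.04 to 0.14; 99.2, 5 higher), as with Ndufa1 and Ndufc1 (1.22 each in CD4 T-like cells) and Cox5a (1.21 in B-like cells). The same list was at -0.05 (31.6, 3 higher) in NK-like and 0.03 (73.4, 1 of 33 higher) in monocyte-like cells.

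Immediate early genes, which respond to stimulation and to cell handling, had members on both sides of 1 in CD4 T-like cells (median -0.12, -0.28 to 0.15; percentile 0.03, 4 of 18 higher, 6 lower). Their members off 1 were lower in NK-like (-0.18, -0.27 to 0.07; 1.27, 7 of 17) and monocyte-like cells (-0.18, -0.42 to 0.02; 2.45, 4 of 16). The medians were -0.01 (15.3, 4 of 17 higher, 7 lower) in CD8 T-like and -0.05 (7.43, 2 of 19 higher, 5 lower) in B-like cells, and -0.07 to -0.03 in the wider monocyte-like classes. Junb stood at 0.757, 0.818, 0.805 and 0.708 in CD4 T-like, CD8 T-like, B-like and monocyte-like cells, and Fos at 0.788, 0.644 and 0.751 in CD4 T-like, CD8 T-like and monocyte-like cells. The actin and migration list had 9 of 22 members higher and 0 lower in B-like cells (0.10, 0.01 to 0.21; 98.7), with Actb at 1.21, Ezr at 1.21 and Pfn1 at 1.14. It stood at 0.02 (67.4, 5 of 23 higher, 2 lower) in CD4 T-like, -0.02 (17.3, 5 of 24 higher, 3 lower) in CD8 T-like, 0.01 (58.0, 3 of 24 higher, 4 lower) in NK-like and -0.04 (30.3, 4 of 23 higher, 1 lower) in monocyte-like cells, where the wider classes gave 0.07 to 0.13. The glycolysis list was at -0.13 (percentile 0.73) in B-like cells, where 1 of 14 members was lower (Eno1, 0.793) and thinning gave -0.00078. It was at 0.06 (78.1, 0 of 13 off 1), -0.04 (10.7, 1 of 15 lower), 0.02 (75.5, 1 of 13 higher) and -0.06 (32.4, 0 of 9 off 1) in CD4 T-like, CD8 T-like, NK-like and monocyte-like cells.

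Naive lymphocyte genes were at -0.02 (32.0, 1 of 14 higher, 2 lower) in CD4 T-like, 0.04 (77.4, 2 higher, 2 lower) in CD8 T-like, 0.07 (72.4, 1 higher, 2 lower) in B-like and 0.18 (99.3, 2 of 11 higher, 1 lower) in NK-like cells, and at -0.04 over 3 genes in monocyte-like cells. With the automatic doublet thresholds the B-like value was -0.35 and the NK-like value -0.08. The cell cycle list was at 0.06 (81.9, 0 of 10 off 1), 0.05 (73.4, 2 of 10 higher, 2 lower), 0.01 (32.6, 1 of 9 lower) and 0.04 (79.2, 2 of 9 higher, 1 lower) in CD4 T-like, CD8 T-like, B-like and NK-like cells, and at -0.27 over 4 genes in monocyte-like cells. Mitochondrially encoded genes were at -0.04 (16.3, 3 of 13 lower), -0.02 (24.7, 4 lower), 0.02 (59.8, 4 higher, 2 lower), -0.01 (35.4, 1 of 12 higher, 1 lower) and 0.07 (78.8, 3 of 10 higher) in CD4 T-like, CD8 T-like, B-like, NK-like and monocyte-like cells, and the last was -0.20 to -0.09 in the wider classes. With each cell thinned to 1000 UMIs, the median number of genes per cell was 527 in mutant and 523 in wildtype CD4 T-like, 518 and 510 in CD8 T-like, 565 and 555 in B-like, 597 and 608 in NK-like and 603 and 605 in monocyte-like cells. An unnamed cluster led by interferon-induced genes held 57 mutant (1.38%) and 56 wildtype cells (1.10%).

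The lower Ly6c2 and Klra9 in mutant NK-like cells prompted the hypothesis that terminally mature NK cells are a smaller part of them. Ctla2a, which had already been named for its ratio, was taken out of the test after its values were seen. The other genes of less mature NK cells had a median log2 ratio of 0.20 (-0.04 to 0.81; 11 genes, percentile 99.4, 2 higher, 1 lower), with the surface protein gene Thy1 at 1.78 and the lymphotoxin gene Ltb at 1.59, but the chemokine gene Xcl1 at 0.661. Genes of mature NK cells had a median of -0.07 (-0.25 to 0.04; 13 genes, 28.9, 1 higher, 2 lower), with the egress receptor S1pr5 at 0.634. The difference between the list medians was 0.27 (0.10 to 0.88, from resampling the genes of each list). It may reflect a less mature mix among the mutant NK-like cells, although each median's own interval included 0. The interval of the difference treats genes as independent. It covers the spread over the chosen genes, and neither counting error nor a difference between genotypes. More T cell RNA in the mutant NK-like cells may also raise the less mature genes, and a list of 10 other T cell markers did not decide this, at -0.0029 (-0.26 to 0.43) with Lef1 at 1.64.

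For the lower class II genes of mutant B-like cells, the hypothesis was a larger part of the cluster with immature B cell genes. A list of 10 class II genes had a median of -0.21 (-0.32 to -0.09) in all B-like cells. Within the largest B-like cluster, which leaves those cells out, it was -0.089 (-0.21 to -0.04). Inside the cluster with immature B cell genes it was -0.17 (-0.46 to 0.12). There H2-Aa (0.781, 0.696 to 0.878) and H2-Eb1 (0.727, 0.624 to 0.850) were lower. H2-Oa (1.26) and H2-Ob (1.10) lay above 1 with intervals that included 1. Class II genes, among them Cd74, H2-Aa and H2-Ab1, were leading genes of the largest B-like cluster. Its cells were thus grouped partly by the tested genes, so the smaller difference there cannot show what the mix adds. A part from the mix and a difference inside the clusters both stay open. For Retnla, 69.4% of the UMIs in mutant cells (530 of 764) sat in 4 cells of the cluster with platelet and dendritic cell genes, the highest with 218. This is consistent with free RNA from a few cells as one source of the Retnla UMIs in the other mutant classes. The wildtype cells held 55 UMIs, 42 of them in 1 cell.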
